A study of Homo sapiens with 8 samples.

How the data were processed

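The series holds 8 RNA-seq libraries of A549, an established human lung adenocarcinoma cell line. The labels place 2 libraries in each of 4 groups: a vector control, overexpression of the long non-coding RNA AFAP1-AS1, a knockdown control and AFAP1-AS1 knockdown. The sample titles call these groups vector, OE, ASONC and ASO. ASO commonly stands for antisense oligonucleotide, in which case the knockdown control was itself treated with an oligonucleotide. Total RNA was the starting material and libraries were made with a commercial RNA-seq kit, per the labels' protocols. Strand use in library preparation and in counting is not given in the sources used here.

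The authors deposited a single table of FPKM values (fragment counts scaled by transcript length and library size), with a column per library and 17056 gene symbols as rows, per the labels and the file header. The submitters' processing notes name HISAT2, featureCounts, HTSeq and R 3.2.0, and the human build hg38 (GRCh38), without saying which tool did which step. The gene annotation, the filters and the reads that enter the library size are not given in the sources used here. Each row was above 0 in at least 1 library, and 16728 of the symbols are protein-coding in the RefSeq gene table used here. Because FPKM divides by the total of a library, a large change in some genes shifts the values of others, which is why other scalings were tried. All 8 columns were mapped to samples by their names.

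Depth was recovered from the values. In nearly every gene the FPKM values of a library were whole multiples of what a single read is worth, and for 17044 genes all values became whole numbers of reads within a tolerance of 0.02 reads. The other 12 genes were highly expressed ones, where that step could not be resolved. The recovered reads summed to between 31709894 and 35297189 per library, and relative depth ran from 1.0 to 1.11. On simulated values the recovery returned the exact reads for 99.2% of 1696 genes read in every library. Of the 17056 genes analysed, 13444 were above 0 in every library, and recovery for genes with a 0 was not scored. A gene above 0 in a single library always comes out as a single read, so its value is whole by construction.

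The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-dependent trend, two-sided) on log2(FPKM + 1), over the 10648 genes with a mean of at least 1 FPKM across the 8 libraries. All 4 groups entered the same fit, which leaves 4 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. They are given with their standard error (SE), and FPKM values as mean ± SD over 2 libraries. Groups of 2 are too small for an exact permutation test to pass the threshold. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The replicates of a group differed by more than sampling noise (chi-square per degree of freedom between 5.03 and 5.77). Such an excess cannot tell separate cultures from repeated libraries of the same culture. They were kept as separate samples.

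Before the data were examined, the tests, 27 gene lists and the rule for named genes were fixed, with 4 comparisons: overexpression against vector control, knockdown against knockdown control, the difference between those effects, and knockdown control against vector control. Lists with at least 5 tested members (25 of 27) were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera asks whether the members move more than other genes do, and its p-values were adjusted over the 25 lists. Camera with an estimated correlation and fry were run beside it. Counts of list members called over all genes are given with the count adjusted over the list alone, except under alternative settings, where the latter was not computed. Genes were named by this rule: AFAP1-AS1, AFAP1 and AXIN2; per comparison the 10 largest changes in each direction among called genes whose libraries do not overlap between groups, or, where fewer passed, all of them and the 5 with the smallest p that did not; up to 4 members of each list with the smallest p; and the genes called in both main comparisons.

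AFAP1-AS1 itself is not analysed here, so the tests planned for it gave no value and the labels could not be checked by the level of the targeted gene. The mitochondrially encoded list had 0 tested members. Splicing cannot be read from values per gene and is not analysed here. Gene positions, lengths and GC content came from GENCODE release 29 on GRCh38, which gave a length and GC value for 99.8% of the genes tested.

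Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a minimum mean of 5 FPKM, median-of-ratios, quantile and TPM scaling, a fit to the compared libraries alone, a replicate block, eBayes without trend and robust, an absolute log2 fold change of at least 1, and leaving out each library in turn. Chosen after seeing the data were limma's voom on the recovered reads, a loess correction of each library for gene length and GC content (span 0.3), and the vector control in place of the knockdown control, the last for counts of genes and lists. Gene by gene values for that swap were left out of the alternatives after they were seen, because it changes the comparison, and the closing section counts how many signs differ.

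The test was tried on simulated data with known changes. For a simulated overexpression comparison of 10625 genes it called 30% of the genes changed by 0.25 on the log2 scale, 88% of those changed by 0.5 and 100% of those changed by 1, and 11 of 10398 unchanged genes. The simulation held 48 to 50 changed genes of each size and gave genes of a similar level the same spread. The real overexpression comparison called 7 genes, so the shares found there may be smaller. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.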

Results

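Transcriptomes of A549 lung adenocarcinoma cells were compared after gain and loss of AFAP1-AS1, a long non-coding RNA transcribed antisense to AFAP1. Each of the 4 groups (vector control, overexpression, knockdown control and knockdown) had 2 libraries, with between 31709894 and 35297189 recovered reads each. Replicates correlated across genes with r between 0.997 and 0.998. The knockdown control libraries stood apart in how many genes they registered. They had 1435 and 1341 of the 17056 genes at 0, against 2205 to 2327 in the other 6 libraries, at a similar depth.

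The title of the series names AXIN2, SR splicing factors and drug resistance, and the targeted locus comes first. AFAP1-AS1 lies on chromosome 4 from 7754090 to 7778928 on the plus strand (GRCh38, GENCODE release 29). AFAP1, which encodes an actin filament-associated protein, runs from 7758714 to 7939926 on the minus strand, and 523 exonic bases are shared, 7.70% of the exonic length of AFAP1-AS1. AFAP1-AS1 itself was not analysed here. AFAP1 had 9.46 ± 0.51 FPKM with the vector control and 13.3 ± 0.12 with overexpression (SD, n = 2), a log2 fold change of 0.45 ± 0.07 (SE) that did not pass the threshold (limma adjusted p = 0.0542) although both libraries were higher. It passed in 7 of 21 alternatives (the fold change threshold, which it does not reach, is not among them), with limma adjusted p-values between 2.48e-07 (voom on recovered reads) and 0.406 (no filter on low genes). AFAP1 had 11.1 ± 0.27 FPKM in the knockdown control and 9.57 ± 0.97 with knockdown, which also did not pass (-0.20 ± 0.07, limma adjusted p = 0.0692, and between 0.00562 and 0.396 over 21 alternatives, of which 2 passed). This value was -0.10 without knockdown replicate 1 (adjusted p = 0.396) and -0.29 without knockdown replicate 2 (adjusted p = 0.0351). The difference between the 2 effects did pass (0.65 ± 0.10, limma adjusted p = 0.00206). Because strand use is not stated, reads of AFAP1 and its antisense partner cannot be told apart where their exons overlap.

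**Figure D1:**
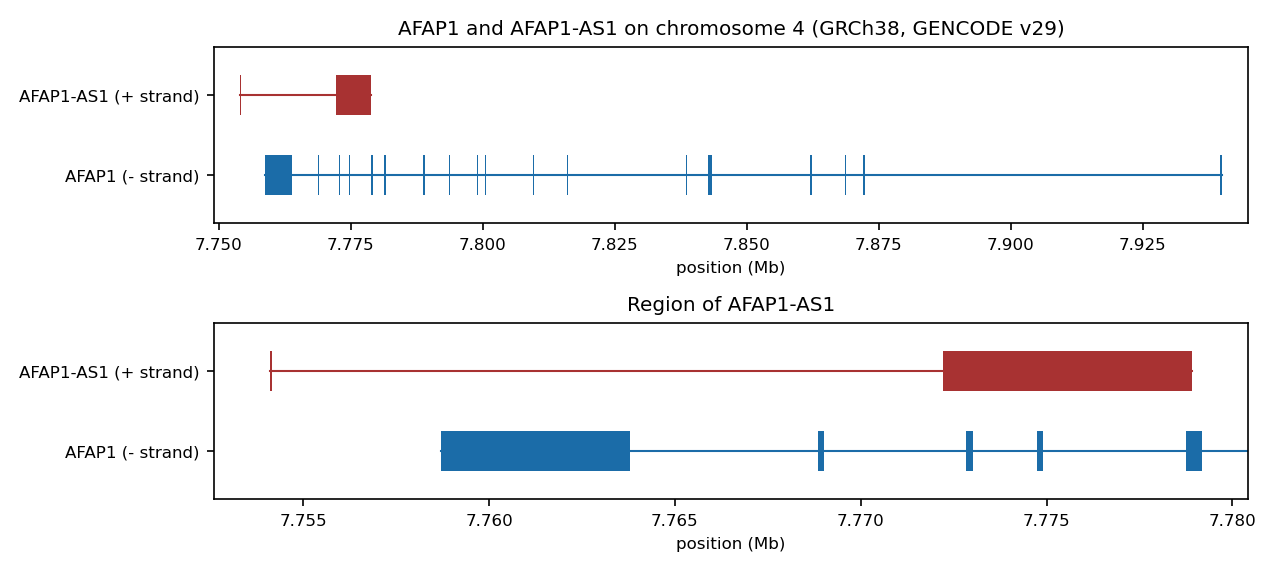
Map of AFAP1 (minus strand) and AFAP1-AS1 (plus strand) on chromosome 4, position in Mb on the x axis, with exons merged over transcripts as boxes and introns as lines. The lower panel enlarges AFAP1-AS1, whose long exon overlaps small exons of AFAP1 over 523 bases in all.

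Overexpression of AFAP1-AS1 raised a small set of genes, nearly all of the interferon response. Of 10648 genes tested, 7 rose and 0 fell (738 had an unadjusted limma p below 0.05). They were IFI27 (0.92 ± 0.12 on the log2 scale), IFI6 (0.73 ± 0.06), IFIT2 (0.71 ± 0.07), IFIT3 (0.69 ± 0.06), IFIT1 (0.59 ± 0.07), ISG15 (0.48 ± 0.05) and RPS28 (0.25 ± 0.04). IFIT1, IFIT2 and IFIT3, neighbours on chromosome 10, encode interferon-induced proteins with tetratricopeptide repeats, and ISG15 on chromosome 1 a ubiquitin-like modifier. IFIT3 went from 15.3 ± 0.47 to 25.2 ± 0.15 FPKM and ISG15 from 35.4 ± 0.63 to 49.7 ± 1.91 (SD, n = 2), with limma adjusted p-values of 0.000522 and 0.000875. RPS28, a ribosomal protein gene (limma adjusted p = 0.0476), has many processed pseudogenes, so its value is uncertain, and it passed in 7 of 21 alternatives. IFI6, IFIT2, IFIT3 and ISG15 each passed in 20 of those 21, all but the one with no filter, and IFI27 and IFIT1 in 17. These 21 leave out the requirement of an absolute log2 fold change of at least 1, under which 0 of the 7 were called.

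Among genes that did not pass, the smallest p-values above 0 fold change after AFAP1 belonged to CCL2 (0.39 ± 0.06), OAS3 (0.30 ± 0.05), IFI44 (0.60 ± 0.10) and HELZ2 (0.47 ± 0.08), and below 0 to CTXN1 (-0.59 ± 0.10), ZSWIM1 (-0.41 ± 0.07), U2AF1 (-2.17 ± 0.41), THYN1 (-0.35 ± 0.07) and HENMT1 (-0.56 ± 0.11). U2AF1, which encodes a splicing factor of the 3' splice site, has a near-identical copy on the same chromosome in this build, so its value depends on how reads were split. The count of 7 rests on the filter and the test: with no filter on low genes 0 of 17056 passed in limma (1033 had an unadjusted p below 0.05), and with voom on recovered reads 27 did, 22 of them higher. Without vector control replicate 2 the count was 12.

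As a group, the interferon response list moved upward with overexpression. All 32 tested members were higher, with a median log2 fold change of 0.33 (quartiles 0.24 and 0.51), and 6 rose over all genes tested and 27 adjusted over the list alone. Camera gave an adjusted p of 1.81e-44, and 0.00346 with an estimated correlation. Genes that encode interferons themselves had few reads in these libraries and did not pass. IFNL1, an interferon lambda gene, had 11 and 27 recovered reads with the vector control and 53 and 46 with overexpression (0.72 ± 0.13, limma adjusted p = 0.124), and IFNB1, which encodes interferon beta, 8 and 8 against 16 and 10 (0.16 ± 0.11, limma adjusted p = 0.86).

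A further 3 lists passed camera with smaller shifts, and their calls were lost with an estimated correlation. Cholesterol synthesis genes had a median of 0.09, with 22 of 25 higher, 0 called and 1 adjusted over the list alone (camera adjusted p = 0.000125, and adjusted p = 0.101 with an estimated correlation); NSDHL, a sterol dehydrogenase gene, was at 0.20 ± 0.04. The G1/S list had a median of 0.06, with 29 of 35 higher, 0 called and 2 adjusted over the list alone (camera adjusted p = 0.000125, and adjusted p = 0.22 with an estimated correlation). E2F1, a transcription factor of S-phase entry, was at 0.24 ± 0.05. The mesenchymal list had a median of -0.05, with 4 of 23 higher, 0 called and 1 adjusted over the list alone (camera adjusted p = 0.00879, and adjusted p = 0.355 with an estimated correlation). PMEPA1 was at -0.18 ± 0.04 and CDH2, which encodes N-cadherin, at -0.18 ± 0.08. Without overexpression replicate 2, the G1/S and mesenchymal lists did not pass (camera adjusted p = 0.0511 and 0.362), and without vector control replicate 2 the mesenchymal list did not (0.0702), in overexpression against vector control.

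The other 21 lists tested did not pass with overexpression (camera adjusted p between 0.0578 and 0.887), and 1 of their members was called, RPS28. Adjusted over the list alone, 3 NF-kB and inflammatory genes, 2 ribosomal protein genes and 1 neighbour on 4p16 rose, and 1 gene each of the hypoxia, YAP/TEAD and snoRNA host lists fell. The SR splicing factors, regulators of exon choice, had a median of -0.002 with 6 of 13 higher (camera adjusted p = 0.835). SRSF9 was at 0.09 ± 0.04 and SRSF5 at -0.07 ± 0.04. The hnRNPs (0.887), Wnt target genes (0.673), Wnt pathway components (0.887), drug efflux transporters (0.647), DNA repair genes (0.689) and p53 targets (0.835) had the camera adjusted p-values given, with 0 members called in each, also adjusted over the list alone. AXIN2, a Wnt target that encodes a scaffold of the beta-catenin destruction complex (chromosome 17, 65528563 to 65561647), had 2.98 and 3.03 FPKM in the vector control libraries and 3.35 and 3.48 with overexpression (0.14 ± 0.11, limma adjusted p = 0.885).

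**Figure D2:**
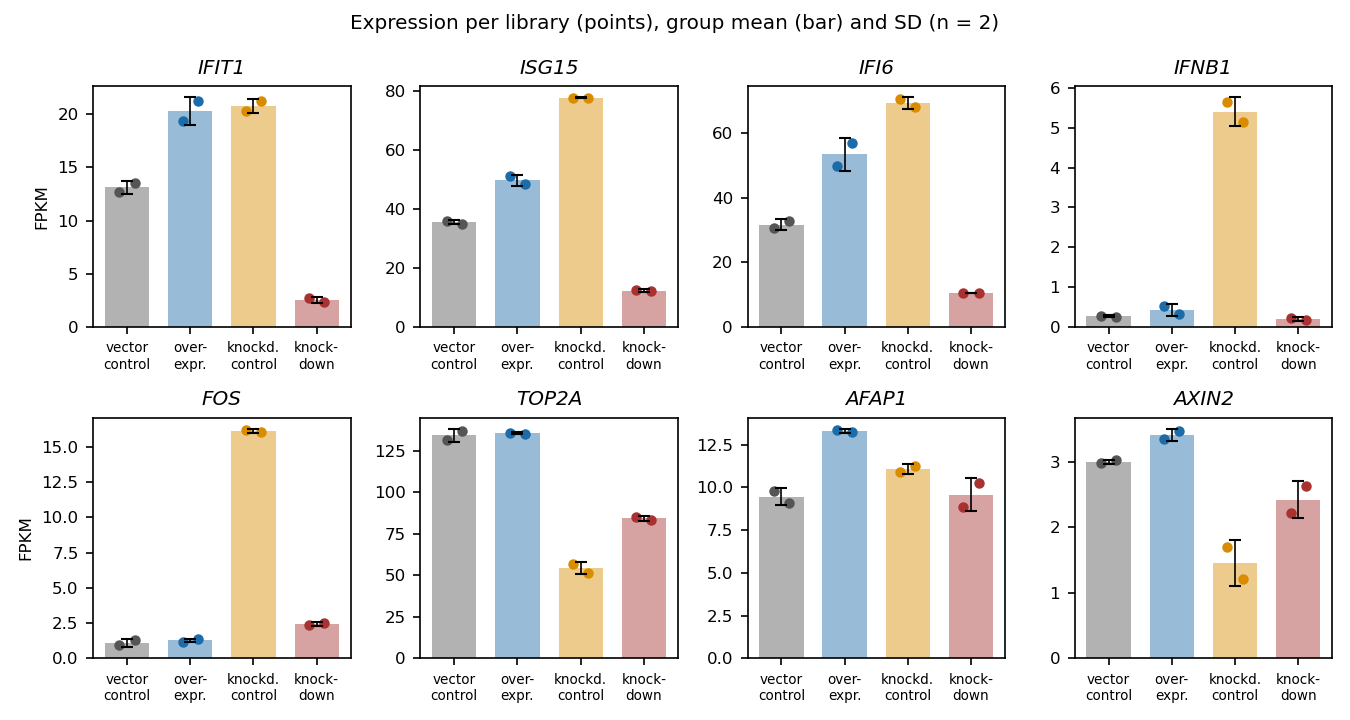
FPKM of 8 genes in each library (points), with the group mean (bar) and SD (error bar, n = 2), in panels with their own y axes from 0. IFIT1, ISG15 and IFI6 were higher with overexpression than with the vector control and were lowest with knockdown, IFNB1 and FOS were high in the knockdown control (5.40 and 16.1 FPKM), and TOP2A was lowest there (54.1 FPKM).

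Knockdown of AFAP1-AS1 changed many more genes against its control. Interferon-induced genes were among those that fell most: IFIT1 from 20.7 ± 0.66 to 2.54 ± 0.26 FPKM (SD, n = 2; -2.62 ± 0.07 on the log2 scale), ISG15 from 77.6 ± 0.07 to 12.3 ± 0.36 (-2.57 ± 0.05) and IFI6 from 69.2 ± 1.80 to 10.5 ± 0.07 (-2.61 ± 0.06). In all 1204 genes rose and 1165 fell (limma adjusted p below 0.05, 2369 of 10648), and 76 genes changed by at least 1 on the log2 scale, all of them lower.

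The 10 largest decreases were in ARC (-4.04 ± 0.09), an immediate early gene, CCL5 (-3.13 ± 0.11), a chemokine gene, LOC105376335 (-3.09 ± 0.14), IFNL1 (-2.63 ± 0.13) and IFNB1 (-2.42 ± 0.11), which encode interferons, and the interferon-induced genes IFIT1, IFI6, ISG15, OASL (-2.42 ± 0.12) and IFIT2 (-2.40 ± 0.07). IFNB1 had 169 and 159 reads in the knockdown control and 7 and 5 with knockdown. The 10 largest increases were smaller: SLC2A3, a glucose transporter gene (0.71 ± 0.06), ACSM3 (0.65 ± 0.08), JMJD1C (0.64 ± 0.07), PDK4 (0.59 ± 0.05), and 6 genes of mitosis and chromosome structure, namely CENPF (0.70 ± 0.05), TOP2A (0.63 ± 0.05), ASPM (0.62 ± 0.07), SMC2 (0.60 ± 0.07), KIF18A (0.59 ± 0.06) and KNL1 (0.59 ± 0.08). CENPF, a kinetochore protein gene, went from 7.14 ± 0.16 to 12.2 ± 0.52 FPKM. All 20 of these had limma adjusted p-values of 0.000307 or less. CENPF, JMJD1C and ASPM were also among the largest decreases of the knockdown control against the vector control (-2.26, -1.89 and -1.86). Across genes, knockdown fold changes followed gene length and GC content (Spearman rho 0.28 and -0.46).

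These calls depend on the control used: against the vector control, 532 of the 2369 were called in the same direction, 1148 in the opposite direction and 689 not at all. Knockdown against vector control called 6700 of all 10648 genes tested (62.9%), the share beside which its counts of list members stand. Leaving out any library of the knockdown or knockdown control group lowered the number of knockdown calls. Such a fit leaves that group with a single library, so its lower power alone would reduce the count. Whether the calls rest on particular libraries cannot be read from it. The share of calls that were higher, 50.8%, was 66.8% with TPM scaling and 62.1% with median-of-ratios scaling.

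Every tested member of the interferon response list fell with knockdown: 32 of 32, with a median of -1.20 (quartiles -2.35 and -0.79) and the same 32 adjusted over the list alone. Camera gave an adjusted p of 9.13e-41, and 0.00411 with an estimated correlation. The knockdown control libraries themselves differed in this list from the vector control (median 0.39, 21 of 32 higher and 6 lower by limma, the same numbers adjusted over the list alone). Against the vector control in place of the knockdown control, all 32 members were lower with knockdown and 30 of them passed in limma, also adjusted over the list alone (median -1.02, camera adjusted p = 8.82e-14, and 0.0174 with an estimated correlation).

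Inflammatory and immediate early genes fell as well. Of 24 NF-kB and inflammatory genes, 17 fell and 0 rose (17 adjusted over the list alone; median -0.37, camera adjusted p = 2.84e-11, and adjusted p = 0.0637 with an estimated correlation), among them CCL5, CXCL2 (-0.80 ± 0.08) and NFKB2 (-0.65 ± 0.04). Of 25 immediate early genes, which respond to stimuli within minutes, 15 fell and 0 rose (15 adjusted over the list alone; median -0.34, camera adjusted p = 2.84e-11, and 0.0481 with an estimated correlation). FOS went from 16.1 ± 0.15 to 2.43 ± 0.13 FPKM (-2.32 ± 0.10), FOSB fell by 2.12 and ATF3 by 1.79 on the log2 scale. Both lists were higher in the knockdown control than in the vector control, with medians of 0.55 and 0.49, and against the vector control the knockdown medians were 0.20 and 0.21 (camera adjusted p = 0.652 and 0.187).

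Stress and p53 genes followed the same direction. Of 26 p53 target genes, 14 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 1.4e-08, and 0.0338 with an estimated correlation). GADD45A fell from 189 ± 10.8 to 63.6 ± 2.18 FPKM (-1.55 ± 0.05), AEN changed by -0.77 ± 0.04 and CDKN1A, the p21 gene, by -0.64 ± 0.04. Of 32 genes of the integrated stress and unfolded protein responses, 15 fell and 3 rose (15 and 4 adjusted over the list alone; median -0.14, camera adjusted p = 0.000249, and adjusted p = 0.21 with an estimated correlation), including DDIT3 (-0.80 ± 0.05), which encodes CHOP, and ASNS (-0.59 ± 0.05), asparagine synthetase. In the knockdown control these lists were higher than in the vector control (medians 0.28 and 0.69). Of the p53 targets 15 were called higher and 5 lower, and of the stress genes 22 and 3, the same adjusted over the list alone. Both list calls (camera adjusted p = 0.0301 and 9.62e-05) were lost with an estimated correlation (camera adjusted p = 0.171 for each). Against the vector control the knockdown medians were -0.05 for p53 targets (camera adjusted p = 0.877) and 0.47 for stress genes (camera adjusted p = 0.00114, and adjusted p = 0.384 with an estimated correlation).

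Cell cycle genes rose with knockdown. Of 35 G2/M genes, 28 rose and 0 fell (32 adjusted over the list alone; median 0.29, camera adjusted p = 7.53e-14, and 0.0481 with an estimated correlation), with ECT2 at 0.55 ± 0.05 and ANLN at 0.46 ± 0.04. Of 35 G1/S genes, 13 rose and 0 fell (20 adjusted over the list alone; median 0.15, camera adjusted p = 3.61e-06, and adjusted p = 0.0637 with an estimated correlation), including the ribonucleotide reductase genes RRM1 (0.27 ± 0.04) and RRM2 (0.27 ± 0.04). Of 37 DNA repair genes, 14 rose and 2 fell (18 and 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.00092, and adjusted p = 0.2 with an estimated correlation), with RAD50 at 0.52 ± 0.06 and BRCA1 at 0.39 ± 0.06. The G2/M list was lower in the knockdown control than in the vector control (median -0.23, 22 of 35 called lower and 7 higher, 23 and 7 adjusted over the list alone), and TOP2A, at 84.3 ± 1.41 FPKM with knockdown, had 131 and 137 FPKM in the vector control libraries. Against the vector control the knockdown medians were -0.01 for G2/M, 0.04 for G1/S and -0.19 for DNA repair (camera adjusted p = 0.383, 0.746 and 0.00177). The DNA repair call was lost there (adjusted p = 0.34 with an estimated correlation).

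Further lists also passed camera with knockdown. Of 73 ribosomal protein genes, 45 fell and 0 rose (51 adjusted over the list alone; median -0.13, camera adjusted p = 2.84e-11, and adjusted p = 0.386 with an estimated correlation), with RPS12 at -0.27 ± 0.03. Their genes have many processed pseudogenes, and against the vector control their median was 0.32 (-0.03 after the length and GC correction, with 27 higher and 30 lower by limma). Against the knockdown control 26 fell and 3 rose after that correction (median -0.06). Of 25 cholesterol synthesis genes, 11 rose and 0 fell (13 adjusted over the list alone; median 0.14, camera adjusted p = 0.000459, and adjusted p = 0.0637 with an estimated correlation), with MSMO1 at 0.36 ± 0.05. The comparison with the vector control called 24 higher and 0 lower (24 and 0 adjusted over the list alone; median 1.06). Of 34 NRF2 target genes, 17 rose and 1 fell (17 and 2 adjusted over the list alone; camera adjusted p = 0.0065, and adjusted p = 0.265 with an estimated correlation), with GCLC, a gene of glutathione synthesis, at 0.53 ± 0.05. With the vector control as reference 11 were called higher and 14 lower (12 and 15 adjusted over the list alone; median -0.06, camera adjusted p = 0.387). Of 13 histone genes 6 fell and 0 rose (8 and 1 adjusted over the list alone; median -0.22, camera adjusted p = 0.00562, and adjusted p = 0.21 with an estimated correlation), and of 22 YAP/TEAD targets 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.0066, and adjusted p = 0.324 with an estimated correlation), CCN2 among those that fell (-0.77 ± 0.07). The histone list was on the other side of 0 against the vector control, with 9 called higher and 1 lower (9 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 0.0808), and of the YAP/TEAD targets 5 were called higher and 9 lower (5 and 9 adjusted over the list alone; median -0.10, camera adjusted p = 0.167). The histone list did not pass with no filter or after the length and GC correction (camera adjusted p = 0.0592 and 0.0931, knockdown against knockdown control).

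The groups closest to the question of the series had list medians nearer 0 with knockdown than the interferon list. Of 13 SR splicing factor genes, SRSF11 rose (0.24 ± 0.05) and SRSF8 fell (-0.28 ± 0.09), the list having a median of 0.05 (1 and 0 adjusted over the list alone; camera adjusted p = 0.588). Measured against the vector control, where 62.9% of all genes tested were called, 3 were called higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.385). Of 25 hnRNPs, 8 rose and 0 fell (9 adjusted over the list alone; median 0.08, camera adjusted p = 0.0211, and adjusted p = 0.276 with an estimated correlation), with PTBP3 at 0.29 ± 0.05. Their direction turned against the vector control, with 4 called higher and 13 lower (4 and 13 adjusted over the list alone; median -0.14, camera adjusted p = 0.0369, and adjusted p = 0.414 with an estimated correlation). The hnRNP call against the knockdown control was lost after the length and GC correction (camera adjusted p = 0.337, knockdown against knockdown control). Of 21 genes of SR protein kinases and nuclear speckle proteins, 8 rose and 1 fell, LUC7L3 among the former (0.42 ± 0.07; 9 and 1 adjusted over the list alone; camera adjusted p = 0.0561). Of these, 0 were called higher and 19 lower against the vector control (0 and 19 adjusted over the list alone; median -0.69, camera adjusted p = 1.86e-08, and adjusted p = 0.244 with an estimated correlation). Of 11 drug efflux transporters, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.208), with ABCC2 at 0.25 ± 0.05 and ABCG2 at 0.20 ± 0.06. In the comparison with the vector control 1 was called higher and 6 lower (1 and 6 adjusted over the list alone; camera adjusted p = 0.0699).

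AXIN2 rose against the knockdown control, from 1.46 ± 0.35 to 2.43 ± 0.29 FPKM (0.48 ± 0.11, limma adjusted p = 0.00712), and passed in 18 of 20 alternatives, which leave out the requirement of an absolute log2 fold change of at least 1 that AXIN2 does not meet. In those 20 the call was lost without knockdown control replicate 2 (0.34, adjusted p = 0.0703) and without knockdown replicate 2 (0.40, adjusted p = 0.0704). AXIN2 was lower in the knockdown control than in the vector control (-0.71 ± 0.11, limma adjusted p = 7.84e-05), and against the vector control knockdown did not pass (-0.23 ± 0.11, limma adjusted p = 0.0772). Of 17 Wnt target genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.609), JUN falling by 0.71 and MYC by 0.17 on the log2 scale. Of 25 Wnt pathway components, 5 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.123), with LRP6, a Wnt co-receptor gene, at 0.43 ± 0.08. The numbers called higher and lower against the vector control were 6 and 2 for Wnt targets (5 and 2 adjusted over the list alone; camera adjusted p = 0.893) and 7 and 11 for pathway components (7 and 11 adjusted over the list alone; camera adjusted p = 0.326).

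The remaining lists did not pass with knockdown. Mesenchymal genes had 3 risen and 6 fallen of 23 (4 and 6 adjusted over the list alone; camera adjusted p = 0.199), with SNAI1, which encodes the repressor Snail, at -1.96 ± 0.13. Epithelial genes had 2 risen and 4 fallen of 19 (2 and 4 adjusted over the list alone; camera adjusted p = 0.588), and hypoxia and glycolysis genes 8 risen and 5 fallen of 29 (8 and 5 adjusted over the list alone; camera adjusted p = 0.819). The 14 neighbours of AFAP1-AS1 on 4p16 had 0 called, also adjusted over the list alone (camera adjusted p = 0.889), the 10 snoRNA host and NMD-sensitive transcripts 1 risen and 2 fallen (1 and 2 adjusted over the list alone; camera adjusted p = 0.819), and the 5 alveolar and secretory lung markers 2 fallen (2 adjusted over the list alone; camera adjusted p = 0.161). Of the leukocyte, endothelial and fibroblast markers 4 were tested and 2 fell (1 rose and 3 fell adjusted over the list alone), CD68 (-0.46 ± 0.04), a lysosomal protein gene that many cell types express, and CD79A (-1.21 ± 0.12).

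**Figure D3:**
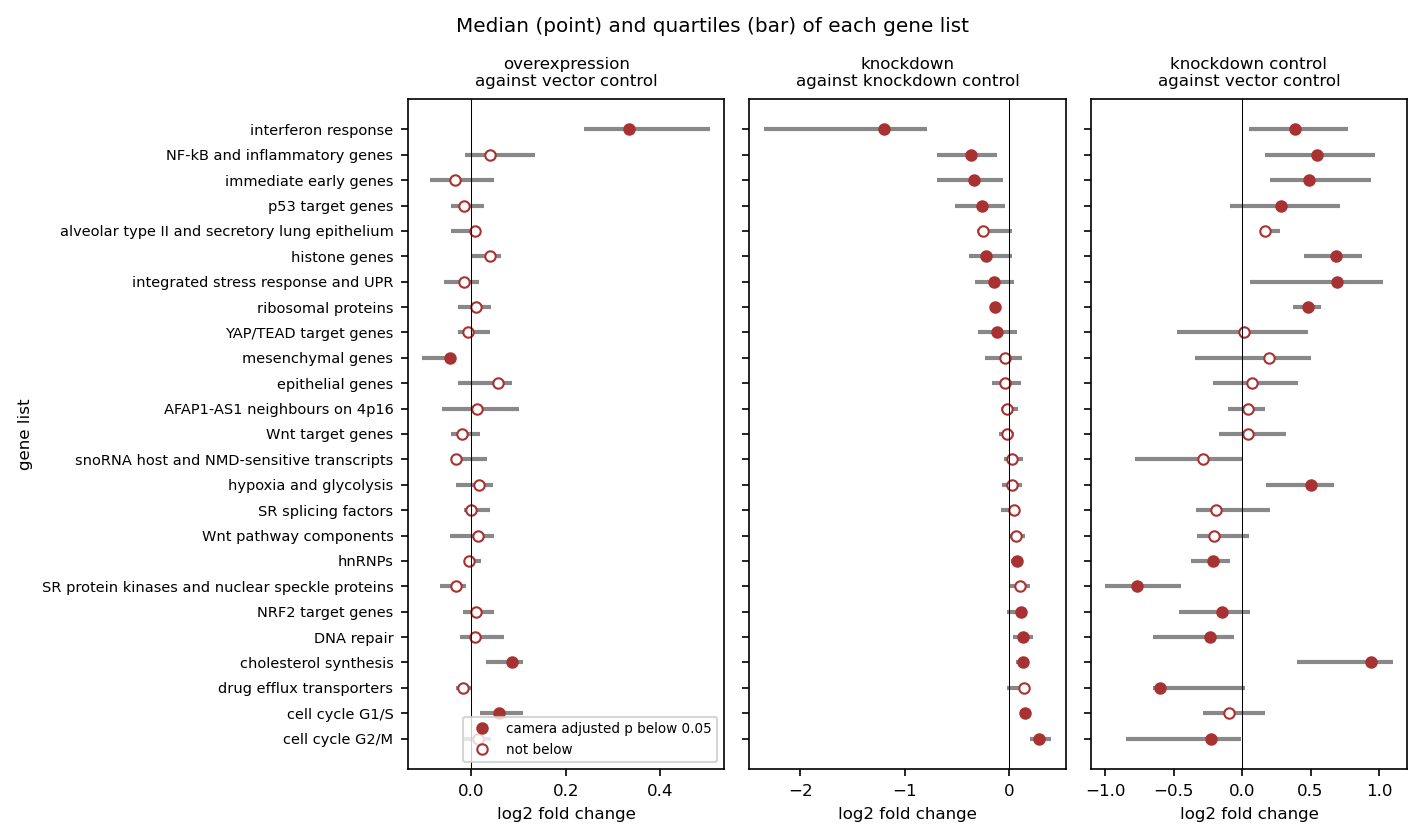
Median log2 fold change (point) and quartiles (bar) of each tested gene list in 3 comparisons, with x axes of different scale, filled points passing camera at an adjusted p below 0.05. The interferon response list lies at 0.33 with overexpression and -1.20 with knockdown.

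Genes that respond in opposite senses to gain and loss of AFAP1-AS1 were counted next. All 7 genes that rose with overexpression fell with knockdown, where independent lists would share 0.766, and the 2 comparisons share no library. Because 6 of the 7 belong to the interferon response list, whose members moved together, they do not count as independent genes and no p-value is given. In knockdown IFI27 changed by -1.69 ± 0.12, IFIT3 by -2.35 ± 0.06 and RPS28 by -0.20 ± 0.04. With no filter on low genes the count was 0, with eBayes without trend 4, and with voom on recovered reads 22.

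The direct test of the overexpression effect minus the knockdown effect called 1087 genes, 659 higher and 428 lower. A gene can be called in it when only 1 of the 2 effects moves, and overexpression against vector control called 7 genes. The 1087 are therefore not a count of genes that moved in opposite senses. All 32 interferon response genes were called in it, also adjusted over the list alone, with a median difference of 1.54 (camera adjusted p = 6.68e-51, and 0.00264 with an estimated correlation). In all 14 of 25 lists passed camera for this difference, and 2 held with an estimated correlation. The p53 targets (14 of 26 called higher and 0 lower, the same adjusted over the list alone, median 0.25, camera adjusted p = 8.04e-08) also held with an estimated correlation (0.0409). The G2/M list (21 of 35 called lower and 0 higher, 27 and 1 adjusted over the list alone, median -0.28, camera adjusted p = 9.4e-12) did not, with an adjusted p = 0.0608 with an estimated correlation. Nor did the NF-kB and inflammatory list (15 of 24 called higher and 0 lower, 16 and 0 adjusted over the list alone, median 0.61, camera adjusted p = 6.74e-12, and adjusted p = 0.0712 with an estimated correlation) or the immediate early list (13 of 25 called higher and 0 lower, the same adjusted over the list alone, median 0.30, camera adjusted p = 7.35e-10, and adjusted p = 0.0608 with an estimated correlation). The medians of the p53, G2/M and immediate early lists had the same sign in both comparisons. They were -0.015, 0.0147 and -0.0354 with overexpression, and -0.255, 0.286 and -0.335 with knockdown. The interferon (0.334 and -1.2) and NF-kB (0.0391 and -0.365) medians had opposite signs. AXIN2 did not differ past the threshold (-0.34 ± 0.15, limma adjusted p = 0.167). Across all 10648 genes the 2 effects were nearly unrelated (Pearson r = -0.121, Spearman rho = -0.0469, across genes, which are not independent replicates). The higher share of the calls, 60.6%, was 41.9% with TPM scaling, 48.1% with median-of-ratios scaling and 72.6% with no filter. The count fell when any of the 8 libraries was left out, which leaves its group with a single library and lowers power.

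**Figure D4:**
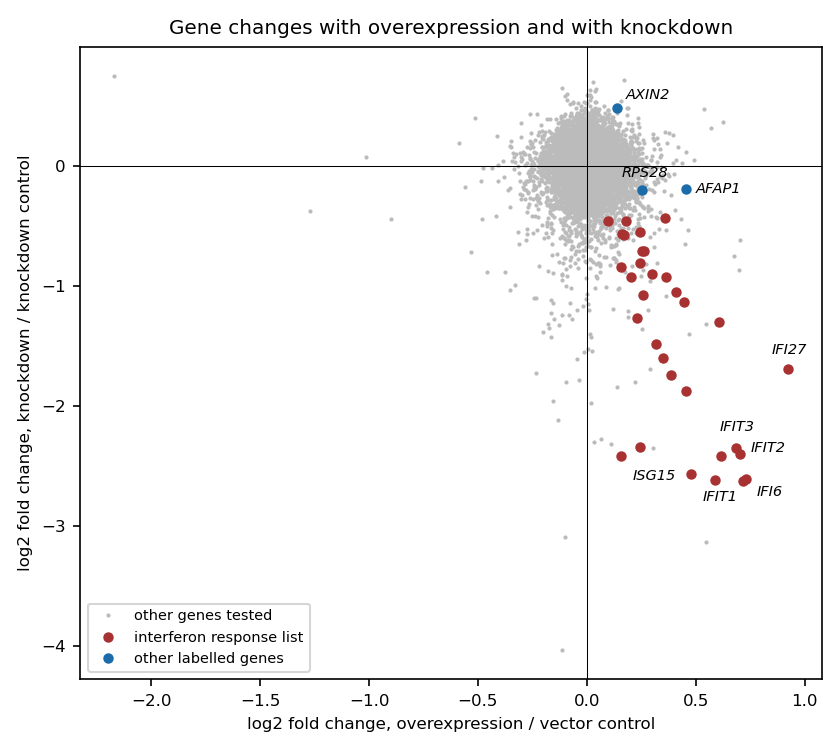
Log2 fold change of each tested gene with overexpression (x axis) and with knockdown (y axis), on the log2(FPKM + 1) scale, with the 32 interferon response genes in red and 3 other labelled genes in blue. All 32 interferon genes lie to the right of and below 0.

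The 2 control groups were compared to measure how far the arms of the study differ apart from the manipulation of AFAP1-AS1. Such differences may come from delivery, reagent or batch. Of 10648 genes, 7309 differed between knockdown control and vector control, 3918 higher and 3391 lower in the knockdown control, and 415 by at least 1 on the log2 scale. The 10 largest increases were in ARC (3.93 ± 0.09), LOC105376335 (3.82 ± 0.14), EGR1 (3.40 ± 0.10), FOS (3.03 ± 0.10), ARL14 (2.87 ± 0.10), FAM71A (2.75 ± 0.10), EGR4 (2.66 ± 0.11), FOSB (2.64 ± 0.09), RRAD (2.45 ± 0.10) and CLDN6 (2.41 ± 0.11), of which EGR1, FOS and FOSB belong to the immediate early list. EGR1 went from 4.64 ± 0.93 to 57.9 ± 1.93 FPKM. The largest decreases were in U2AF1 (-2.31 ± 0.41), CENPF (-2.26 ± 0.05), JMJD1C, ASPM, ATRX, GOLGA4, CENPE, PNN, NRIP1 and TPR (-1.89 to -1.72).

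By list, with the same numbers of calls in each of the following 4 lists adjusted over the list alone, cholesterol synthesis genes were higher in the knockdown control (23 of 25 called, median 0.94, camera adjusted p = 3.62e-08, and adjusted p = 0.0677 with an estimated correlation), as were immediate early genes (18 of 25 called higher and 1 lower, camera adjusted p = 5.1e-05, and adjusted p = 0.171 with an estimated correlation). SR protein kinases and nuclear speckle proteins were lower (18 of 21 called, median -0.77, camera adjusted p = 1.24e-07, and adjusted p = 0.171 with an estimated correlation). Ribosomal protein genes were higher (69 of 73 called, median 0.48, camera adjusted p = 1.28e-13, and adjusted p = 0.317 with an estimated correlation), but after the length and GC correction 34 were called higher and 26 lower with a median of 0.02. In all, 15 of 25 lists passed, and 0 held with an estimated correlation. TPM scaling moved the median of all genes from 0.04 to -0.16 and the higher share of calls from 53.6% to 31.7%. The vector and knockdown arms cannot be linked through any library, so the control difference is not separable from other differences between the arms.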

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

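The voom, length and GC, and swapped-control alternatives were chosen after the data were seen, and the others before. No alternative could be run for AFAP1-AS1. Unless named here, total counts of calls (not those of each direction) stayed within 1.5 times their main values, and where a count moved the cause was not tested beyond what the setting itself changes. With no filter, overexpression called 0 genes in limma (1033 of 17056 at an unadjusted p below 0.05; voom called 27) and 0 moved in opposite senses (7 and 7 as reported), and of 2274 knockdown calls 39.3% were higher (50.8% as reported) and 1619 were among the reported 2369. With a minimum mean of 5 FPKM overexpression called 11, with eBayes without trend 4 and with robust eBayes 14, and of the last pair 4 and 12 were opposite in knockdown. Without trend the difference of effects called 659. Its share of higher calls, 60.6% as reported, was 72.6% with no filter, 41.9% with TPM and 48.1% with median-of-ratios scaling, and that of the control groups 31.7% with TPM instead of 53.6%. Requiring an absolute log2 fold change of at least 1 left 0 genes for overexpression (3 at an unadjusted p below 0.05), 76 for knockdown, 88 for the difference, 415 for the control groups and 0 opposite. Voom on recovered reads called 27 for overexpression, 1698 for the difference (47.6% higher instead of 60.6%) and 22 opposite, and included all 7 main overexpression calls. The length and GC correction called 12, 703 and 11 for the same 3 results, again with all 7 main overexpression calls. With the vector control in place of the knockdown control, knockdown called 6700 genes and 8 lists instead of 2369 and 14, and 1148 of the 2369 were called in the opposite direction, 532 in the same direction. Of 117 genes named for knockdown, 69 had the opposite sign under that swap (63 of the 106 called), and the gene by gene comparisons here leave the swap out, a choice made after this was seen. Camera with an estimated correlation left 1 list for overexpression (interferon response) and 4 for knockdown, and fry called 4 and 18.

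Leaving out each library in turn, where the lone library of a group is assumed to vary like the others, gave 6 to 12 genes for overexpression (12 without vector control replicate 2), 1176 to 2315 for knockdown, 609 to 823 for the difference, 6517 to 7282 for the control groups, 5 to 9 opposite genes, 2 to 6 lists for overexpression (2 without overexpression replicate 2) and 14 to 15 for knockdown. Same-numbered libraries of different groups did not deviate together (correlations of -0.061 to 0.062). No pairing by number was seen in the values, but whether such libraries were prepared together is not in the labels. With the replicate block the counts were 8 for overexpression, 2315 for knockdown, 1080 for the difference, 7320 for the control groups and 7 opposite, with 4 and 14 lists. Outside the swap, HNRNPA3 was the only called gene among those named to change sign, at -0.015 in knockdown after the length and GC correction. Over all alternatives of the named genes, 2333 values for overexpression and 2296 for knockdown kept sign and side of the threshold, 26 and 117 lost the call, and 36 and 23 gained it. Depth was similar in all libraries, between 31709894 and 35297189 recovered reads. In the simulated overexpression comparison of 10625 genes 30% of changes of 0.25 on the log2 scale were called, so changes of that size are often missed.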

Other observations

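The tests below were chosen after the results were seen, except those of the shared control libraries and of the number of silent genes with 10 or more reads.

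Knockdown against vector control, a comparison added after the data were seen, showed gene groups in which the knockdown arm as a whole differed from the vector arm. Cholesterol synthesis genes were all higher with knockdown and 24 of 25 passed in limma (24 adjusted over the list alone; median 1.06, camera adjusted p = 9.53e-12, and 0.0174 with an estimated correlation), against a median of 0.94 for the knockdown control. Hypoxia and glycolysis genes were called higher in 21 of 29 and lower in 3 (22 and 4 adjusted over the list alone; median 0.59, camera adjusted p = 4.01e-05, and adjusted p = 0.0602 with an estimated correlation). SR protein kinases and nuclear speckle proteins were called lower in 19 of 21 (19 adjusted over the list alone; median -0.69, camera adjusted p = 1.86e-08, and adjusted p = 0.244 with an estimated correlation). These medians kept their sign under median-of-ratios, quantile and TPM scaling and after the length and GC correction, relative to a median of all genes that TPM scaling moved from 0.03 to -0.13.

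U2AF1 had 9.20 ± 0.37 FPKM with the vector control, 1.32 ± 0.70 with overexpression, 1.06 ± 0.11 in the knockdown control and 3.17 ± 3.31 with knockdown (SD, n = 2).

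The interferon response list rose with overexpression and fell with knockdown. A trend with gene length and GC content is not the whole cause, since after its removal the list medians were 0.328 with overexpression and -1.22 with knockdown, beside 0.33 and -1.20 before, and both still passed camera. The hypothesis that these genes follow the level of AFAP1-AS1 predicts opposite senses, and 32 of 32 members moved so in comparisons that share no library. But it was found on the same data, AFAP1-AS1 was not analysed here, and members that move together are not independent observations. The list was also higher in the knockdown control than in the vector control (median 0.39, 21 of 32 called higher and 6 lower). That median is not below the 0.33 of overexpression, although the labels give both groups as controls. A raised interferon state of the knockdown control libraries, in which IFNB1 was at 5.40 FPKM against 0.27 with the vector control, may account for part or all of the fall with knockdown. That cannot be told apart from an effect of the knockdown: the list was lower than in the vector control (median -1.02), but no untreated library of the knockdown arm was analysed here to show the baseline of that arm.

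The control groups differed in 7309 genes, and the knockdown changes ran against that difference: 2058 of the 2369 knockdown calls (86.9%) had the opposite sign. Of the genes called in both, 923 fell with knockdown and were higher in its control, where independent lists give 429, and 890 rose and were lower, where they give 383. Part of this excess may come from the shared control libraries, since 66.6% of simulated unchanged genes had opposite signs. That share is over all simulated genes, called or not, with no difference between groups. It is therefore not the share to expect among called genes, and the size of that part was not tested. The covariance of the fold changes, -0.0682 (r = -0.59), was beyond the -0.00399 (r = -0.49) that 100 simulations of unchanged groups sharing those libraries gave. This argues against independent chance values of single libraries as the whole cause. The simulation drew noise separately for each library, so it cannot speak to a deviation common to both knockdown control libraries. Fold changes also followed gene length and GC content (Spearman rho -0.52 and 0.53 for the control groups, 0.28 and -0.46 for knockdown), but 4430 of 7309 and 1284 of 2369 genes were still called in the same direction after correction (359 of the former turned direction), so this trend is not the whole cause either. A stress response of the knockdown control cells, with immediate early genes at a median of 0.488 against the vector control, cannot be told apart from other differences between the arms, because no library links the arms.

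In the knockdown control, 198 genes were read in both libraries and in none of the other 6, against 7 to 11 for the other groups. Greater depth is argued against, since the deeper knockdown control library had a relative depth of 1.09 and an overexpression library 1.11 with fewer genes read. Genomic DNA, which would spread reads over silent genes by their length, cannot be told apart from other sources, because the tests disagree over a wider set, the 708 genes with a known length that had no read in the other 6 libraries. Of these, 69 genes had 10 or more reads where a Poisson spread by length gives 72, a test set before its result was seen. That count does not show whether the genes with more reads were the longer ones, and its rate was not fitted with genes at 0 left out. In a test chosen afterwards, the Spearman rho between reads and length was 0.124 over the 683 genes with an estimated read. This lies below the 0.712 to 0.784 of 100 simulations fitted with genes at 0 left out. The mean level in the 708 genes was 0.0313 FPKM, and a biological source was not tested.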
